A study of Mus musculus with 6 samples.

How the data were processed

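RNA-seq had been run on mouse intestine tissue of 2 genotypes, HET and WT, with 3 libraries each. Per the labels' protocols, RNA was captured on oligo(dT) beads and libraries were made with a SMARTER mRNA kit. The submitters' processing notes name the genome build GRCm39, while the aligner, the counting tool, their versions and the annotation are not given in the sources used here. The values used are FPKM, as the authors deposited them in 1 table with 1 column per library, named as the samples are titled. FPKM divides each gene's fragments by its transcript length and by the library's total, so a change in a few abundant genes shifts all others. A count table that the labels mention was not used here. Whether the counting used strand is not given in the sources used here, so fragments of overlapping antisense genes cannot be told apart.

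The table held 25416 rows, of which 22036 carried an Ensembl gene identifier and 3380 were unnamed loci. Symbols of 11 rows had been turned into dates and were restored from their identifiers, and 22022 identifiers were found in the GENCODE M21 gene names. That reference is on GRCm38, not on the build of the values, so it was used only for gene names, transcript length and GC content, and RefSeq genes of GRCm38.p6 only for synonyms and for which genes neighbour each other. No coordinates are given. A symbol was held by more than 1 row in 19 cases, and 8 list genes were matched through a synonym. No 2 libraries held identical values (0 pairs).

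Sequencing depth was estimated from the lowest values: FPKM times transcript length in kilobases piles up at the worth of 1 fragment, which implied 19700000, 21900000 and 19500000 fragments in HET replicates 1 to 3 and 20700000, 25000000 and 25800000 in WT replicates 1 to 3. These are rough estimates, since reference lengths differ from those the authors used and the search was limited to a preset range. Genes near 1 fragment were also compared with HET replicate 1, with 39 to 73 genes for each other library. Only 21.9% to 33.3% of their ratios lay within 5% of the median ratio. Exact values of 0 were held by 7295 to 7460 rows in HET and by 6295 to 6688 rows in WT, and a gene at 0 is described as listed at 0. All 4 Y-linked genes looked up were at 0 in every library.

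Genes with FPKM of at least 1 in at least 3 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using eBayes with a mean-variance trend and Benjamini-Hochberg adjusted p under 0.05. Genotype was the only term. The test was tried on simulated values, with 1 table per size of change, built for 11870 genes with each gene's own spread and 200 changed genes. It recovered 49.0% of the changes of 0.5 on the log2 scale and 95.5% of those of 1. Far more genes were called in the data (5504), so these shares need not hold there. Before the data were examined, 54 gene lists of pathways and cell types were fixed, and the lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. On simulated values the list test at the preset correlation recovered the 1 shifted list and called 0 others. Those values were drawn independently for each gene, so they do not check the list test on correlated genes. A position score was the mean log2 level of the distal small-intestinal list minus that of the proximal list. Rnf111 was also compared with an exact two-sided permutation test. Versions of the other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

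The genes named in the text follow a rule fixed in advance: Rnf111, then in each direction the 12 genes with the largest log2 fold change among called genes whose HET values all lay on one side of the WT values, then up to 4 measured members with the largest moderated statistic for each called list and for the TGF-beta and BMP lists. Predicted models and unnamed loci were counted and not named, and some genes that the rule takes are not reported here. Genes chosen after their values were seen are said to be so, apart from members named, also after their values were seen, because at most 5 of their list moved in that direction. For each named gene past the threshold, all 3 HET values lay on one side of all 3 WT values.

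Alternatives were other pseudocounts (0.1 and 0.01), no filter on low values, a mean FPKM of at least 5, 3 other scalings, the replicate number as a block, array weights, eBayes without trend or robust, and leaving out each library. Correction for length and GC content, leaving out unnamed loci, and the position score as a covariate were added after seeing the data. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. The labels give no batch, sex, age or segment of the intestine, so genotype and any unlabelled batch cannot be told apart.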

Results

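Polyadenylated RNA from mouse intestine was sequenced from 3 libraries of the genotype labelled HET, which carried the S254D substitution in Rnf111, and from 3 libraries labelled WT. Each transcript level was given as FPKM, fragments normalised to transcript length and to the library's total. Rnf111, also called Arkadia, encodes a ubiquitin ligase known to enhance TGF-beta signalling by marking the inhibitors Smad7, Ski and Skil (SnoN) for degradation. The comparison addressed which transcripts of the intestine differed between the genotypes. Summed FPKM lay between 469968 and 510568 in the HET libraries and between 493950 and 520095 in the WT libraries. The sequencing depth implied by the lowest FPKM values, a rough estimate, was 19500000 to 21900000 fragments in HET and 20700000 to 25800000 in WT. Between 10989 and 11073 rows reached an FPKM of 1 in the HET libraries, against 11923 to 12067 in the WT libraries. Transcripts encoded by the mitochondrial genome held 15.4% to 18.3% of the summed FPKM in HET and 13.9% to 15.5% in WT. Unless stated otherwise, values are mean FPKM ± SD with n = 3 libraries per genotype, fold changes are ratios of mean FPKM, and log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes.

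All 19 measured genes of Paneth cells, the antimicrobial secretory cells of the crypt base, fell in the HET libraries, as did all 25 of the extracellular matrix and all 17 of smooth muscle. So did 11 of 13 fibroblast, 15 of 16 endothelial, 18 of 19 T and NK cell and 11 of 12 plasma cell genes. These lists were called with a preset correlation between genes, and 0 lists were called with an estimated one. The mast cell proteases Mcpt1 and Mcpt2 and the metallothioneins Mt1 and Mt2 rose, as did Angptl4, Pdk4 and Pck1. Ang4, an antimicrobial angiogenin of Paneth cells, was at 6.46 ± 7.31 in HET and 682 ± 382 in WT, a fold of 106 that was 301 without HET replicate 3. Col1a1, a chain of type I collagen, was 8.02-fold lower in HET (1.16 ± 0.275 against 9.31 ± 0.1). Mcpt1, a mucosal mast cell protease, was 24.7-fold higher (33.6 ± 13.0 against 1.36 ± 0.509). Fkbp5, a co-chaperone of the glucocorticoid receptor that glucocorticoids induce, was 10.8-fold higher (36.0 ± 0.302 against 3.32 ± 0.164).

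Rnf111 itself was at 4.43, 4.83 and 4.25 FPKM in the 3 HET libraries and at 4.97, 5.29 and 5.34 in the 3 WT libraries. Its log2 fold change was -0.17 (SE 0.06, 95% confidence interval -0.32 to -0.02) with a limma adjusted p of 0.0609. The difference did not pass the threshold. The exact two-sided permutation test over 20 arrangements gave p = 0.1, the smallest value that 3 against 3 libraries allow. With median-ratio scaling the log2 fold change was -0.09 and the permutation test gave p = 0.2. The substitution changes the encoded protein, and the transcript level does not check which libraries carry it.

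Of 11870 genes tested, 1269 were higher and 4235 were lower in HET at a limma adjusted p under 0.05 with Benjamini-Hochberg adjustment. An unadjusted p under 0.05 was reached by 6465. Of the called genes, 85 were higher and 439 were lower by more than 2-fold on the log2(FPKM + 1) scale. The HET values lay wholly on one side of the WT values for 5487 of the 5504 called genes and for 7093 of all tested genes, where chance gives 10%. The median log2 fold change of all tested genes was -0.12, and quantile normalization moved it to 0.04. List medians are therefore given relative to the median of all tested genes. An upward call thus means higher than other genes, and members of such a list may have changed little. The balance of calls moved with the scaling. With FPKM as deposited, 76.9% of the called genes were lower, and with a common sum per library 66.9% were (1736 higher, 3509 lower). The share was 58.3% (2334 higher, 3267 lower) with median-ratio scaling and 42.4% (2929 higher, 2153 lower) with quantile normalization. Unnamed loci made up 522 of the tested rows, of which 60 were higher and 236 lower. They held 2.67% to 3.62% of the summed FPKM in HET and 5.90% to 6.12% in WT.

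**Figure D1:**
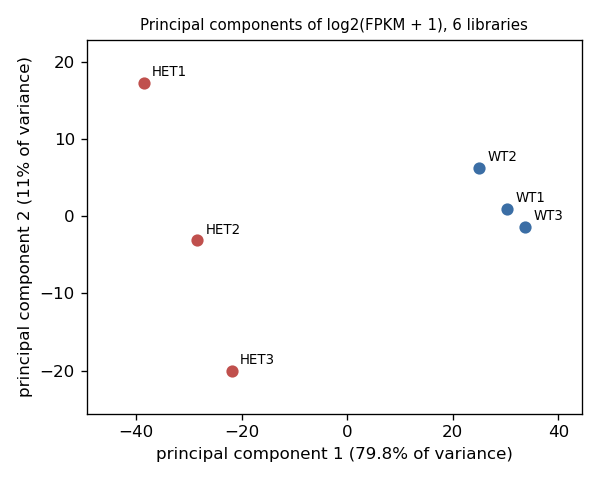
Principal components 1 and 2 of log2(FPKM + 1) of the tested genes, with 1 point per library, HET in red and WT in blue. Component 1 held 79.8% of the variance and parted the genotypes, and component 2 held 11% and spread the 3 HET libraries.

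The libraries split by genotype along the first principal component, which held 79.8% of the variance. Pearson correlations of log2 values across genes were 0.981 to 0.993 among the HET libraries, 0.992 to 0.996 among the WT libraries and 0.939 to 0.969 between genotypes. Genes are not independent replicates. The median SD per gene on the log2 scale was 0.10 in HET and 0.07 in WT.

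All 19 measured Paneth cell genes fell, and all 19 passed when adjusted over the list alone. Their median log2 fold change was -4.74 relative to all tested genes (camera, adjusted p = 0.000184, and adjusted p = 0.597 with an estimated correlation). The 12 largest falls under the naming rule were Ang4, Mptx2, a pentraxin of Paneth cells, and 10 members of the alpha-defensin family, antimicrobial peptides of Paneth granules. These were Defa31, Defa23, Defa29, Defa30, Defa3, Defa17, Defa36, Defa37, Defa24 and the defensin-like AY761184. Defa24 was at 216 ± 215 in HET and 4822 ± 2240 in WT (limma adjusted p = 0.0024), and Mptx2 was at 6.31 ± 7.94 and 373 ± 221 (adjusted p = 0.00227). Alpha-defensin paralogs are near-identical in sequence, so the split of fragments among single defensins is uncertain. Itln1, the lectin intelectin-1, was 15-fold lower (66.6 ± 34.9 against 999 ± 553, adjusted p = 0.0016). Lyz1, the Paneth cell lysozyme, was named after its values were seen, at 136 ± 138 against 1812 ± 784 (adjusted p = 0.00434). Paneth levels varied between libraries of a genotype: Ang4 was at 1.45, 3.08 and 14.8 FPKM in HET replicates 1 to 3 and at 720, 282 and 1044 in WT replicates 1 to 3. Without HET replicate 3 the fold of Mptx2 went from 59.1 to 206, that of Lyz1 from 13.3 to 31.3, and the folds of the 10 alpha-defensin family members moved by 2.03 to 4.49 times, all further from 1. A score of distal minus proximal small-intestinal markers was -1.80, -0.97 and -0.35 in the same HET libraries and -0.47, -0.80 and -0.25 in the same WT libraries.

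**Figure D2:**
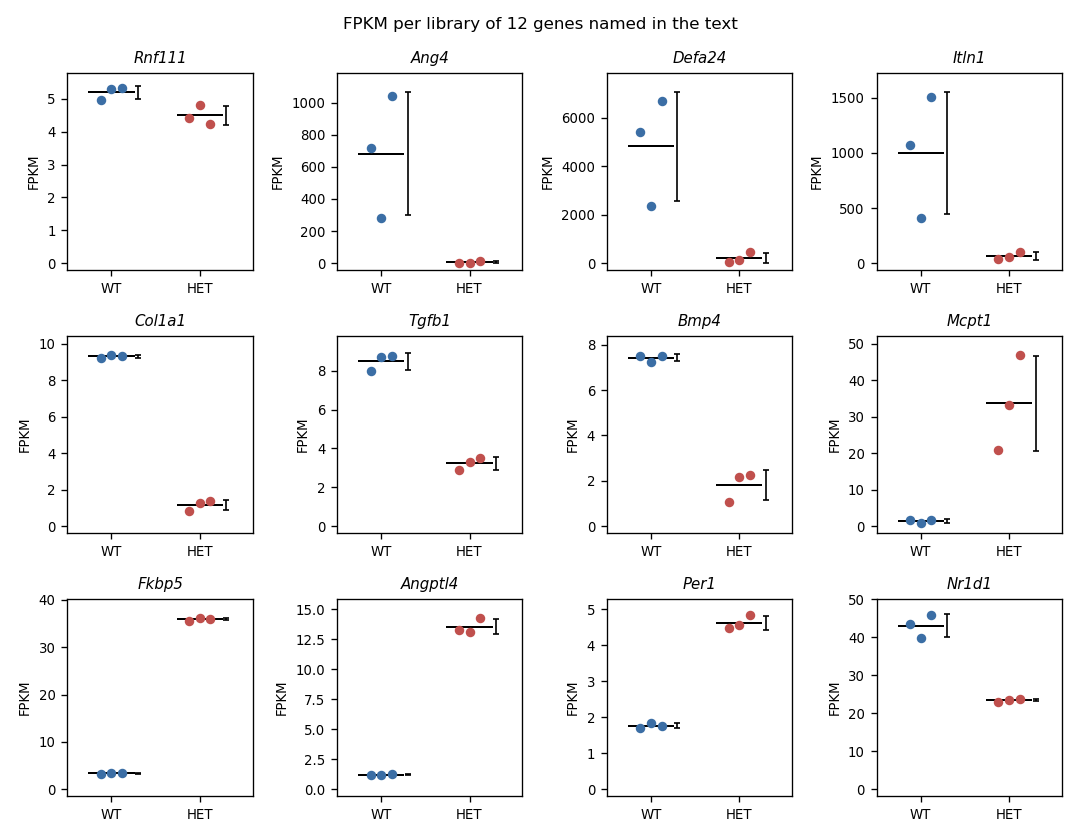
FPKM per library of 12 genes named in the text, WT in blue and HET in red, each panel with its own linear axis, with a horizontal line at the mean of 3 libraries and a bar of 1 SD to either side. The HET points lie below the WT points for Rnf111, Ang4, Defa24, Itln1, Col1a1, Tgfb1, Bmp4 and Nr1d1 and above them for Mcpt1, Fkbp5, Angptl4 and Per1, and Rnf111 did not pass the threshold.

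Genes of the connective tissue fell together. Each of the 25 measured genes of the extracellular matrix list fell, with a median log2 fold change of -1.35 relative to all tested genes (camera, adjusted p = 5.41e-10, and adjusted p = 0.553 with an estimated correlation). Lum, a collagen-binding proteoglycan, was 4.81-fold lower (1.12 ± 0.0883 against 5.38 ± 0.459, limma adjusted p = 4.27e-05), Col5a2 was 4.70-fold lower and Col5a1 4.94-fold lower. Of 13 fibroblast genes 11 fell, with a relative median of -1.47 (camera, adjusted p = 4.51e-05, and adjusted p = 0.553 with an estimated correlation). Clec3b and Dpt, matrix proteins of fibroblasts, were 6.43-fold and 4.83-fold lower (1.72 ± 0.145 against 11.1 ± 0.324, and 3.38 ± 0.243 against 16.3 ± 1.27). Adjusted over the list alone, the counts were again 25 and 11.

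Smooth muscle and vessel genes fell by less. All 17 smooth muscle genes fell, with a relative median of -0.60 (camera, adjusted p = 2.31e-05, and adjusted p = 0.553 with an estimated correlation). Acta2, smooth muscle actin, was at 57.5 ± 4.87 in HET and 101 ± 5.97 in WT, Mylk, myosin light chain kinase, was 1.66-fold lower, and Flna, filamin A, and Tagln, transgelin, were 2.17-fold and 1.69-fold lower. Of 16 endothelial genes 15 fell, with a relative median of -0.49 (camera, adjusted p = 0.00106, and adjusted p = 0.563 with an estimated correlation). Pecam1, an endothelial adhesion molecule, was at 4.36 ± 0.880 in HET and 8.95 ± 0.560 in WT, and Eng, a TGF-beta co-receptor, was 1.85-fold lower. Adjusted over the list alone, 17 and 15 members passed.

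Of 21 measured TGF-beta pathway components, 12 fell, 1 rose and 8 did not pass, while 15 fell and 1 rose when adjusted over the list alone. Their relative median was -0.14 (camera, adjusted p = 0.0149, and adjusted p = 0.576 with an estimated correlation). The ligand Tgfb1 was 2.62-fold lower (3.24 ± 0.330 against 8.496 ± 0.437, limma adjusted p = 0.000127), the receptor Tgfbr1 was 2.00-fold lower (2.53 ± 0.158 against 5.05 ± 0.306, adjusted p = 0.000272). The co-receptor Tgfbr3 and the latent ligand-binding protein Ltbp3 were 2.70-fold and 3.45-fold lower. The known protein substrates of Rnf111 were singled out after their values were seen. Smad7 transcripts fell (5.16 ± 0.796 against 8.84 ± 0.735, adjusted p = 0.00265), as did Skil transcripts (6.66 ± 2.06 against 12.05 ± 0.599, adjusted p = 0.0125). Ski did not pass (9.94 ± 0.617 against 10.9 ± 0.347, adjusted p = 0.143). Axin1, a scaffold of Wnt and TGF-beta signalling, was the member that rose (13.1 ± 0.138 against 11.2 ± 0.260, adjusted p = 0.0114).

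Of 20 TGF-beta target genes, 18 fell and 1 rose, both over all tested genes and adjusted over the list alone, with a relative median of -0.64 (camera, adjusted p = 5.47e-05, and adjusted p = 0.553 with an estimated correlation). Col3a1 (4.24 ± 1.22 against 28.4 ± 2.12), Col1a2 (2.76 ± 0.846 against 12.7 ± 0.822), Col1a1 and Col5a1 led the list. Bhlhe40, a transcription factor also counted among the clock genes, rose (28.5 ± 1.67 against 19.6 ± 1.35). The matrix, fibroblast and smooth muscle lists also held 7 of these 20 genes. Of the other 13, 11 fell and 1 rose. Whether connective tissue or immune cells also express those 13 was not examined. This split therefore does not separate a change in TGF-beta signalling from the fall of connective tissue and immune cell genes. The same holds for the TGF-beta components and the BMP genes. Smad7 and Skil were members of both TGF-beta lists. Of 16 genes of the BMP pathway, 10 fell and 1 rose, over all tested genes and adjusted over the list alone, but the list was not called (relative median -0.29, camera, adjusted p = 0.0871). The ligands Bmp4 (1.82 ± 0.662 against 7.43 ± 0.158) and Bmp5 (1.21 ± 0.526 against 5.05 ± 0.514), the inhibitor Smad6 and the antagonist Grem1 fell, by 4.08-fold, 4.18-fold, 1.80-fold and 1.86-fold. Bmp5 was among the 50 tested genes nearest to Rnf111. The ligand Bmp2 was the member that rose (6.35 ± 0.991 against 4.40 ± 0.134).

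T cell, plasma cell and macrophage genes fell. Of 19 T and NK cell genes 18 fell (relative median -0.57, camera, adjusted p = 4.58e-05, and adjusted p = 0.553 with an estimated correlation). Among them were Cd3e (4.86 ± 0.725 against 11.01 ± 0.412), Cd4, Cd8b1 and Itgae, an integrin of intraepithelial lymphocytes. Of 12 plasma cell genes 11 fell (relative median -0.94, camera, adjusted p = 0.00106, and adjusted p = 0.553 with an estimated correlation). Among these were the light chain constant gene Iglc2 (20.2 ± 2.60 against 50.7 ± 2.06), Irf4, Eaf2 and Derl3. Of 15 macrophage and dendritic cell genes 11 fell (relative median -0.64, camera, adjusted p = 0.0176, and adjusted p = 0.615 with an estimated correlation). They included the receptor Csf1r (7.58 ± 1 against 17.0 ± 0.470), Cx3cr1, Adgre1 and Aif1. Adjusted over the list alone, 19, 11 and 11 members fell. Of 26 interferon-stimulated genes 15 fell and 1 rose, or 16 and 1 adjusted over the list alone (relative median -0.47, camera, adjusted p = 0.0124, and adjusted p = 0.651 with an estimated correlation). They included Mx1, Ifit2, Ifih1 and Rsad2, which was 6.95-fold lower, and the GTPase Igtp was the member that rose (181 ± 33.6 against 90.4 ± 16.3).

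Of 6 mast cell genes 5 rose and 1 fell, over all tested genes and adjusted over the list alone, with a relative median of 1.44 (camera, adjusted p = 2.76e-05, and adjusted p = 0.553 with an estimated correlation). Mcpt2, another mucosal protease, was 18.7-fold higher (9.77 ± 3.45 against 0.523 ± 0.0423, limma adjusted p = 0.000206). Cpa3, a mast cell carboxypeptidase, was at 1.86 ± 0.269 against 0.128 ± 0.0611, and Fcer1a, a chain of the IgE receptor, at 1.71 ± 0.109 against 0.0950 ± 0.0489. The protease Mcpt4 also rose. Kit, the stem cell factor receptor that interstitial cells of Cajal also carry, was the member that fell (1.48 ± 0.216 against 2.28 ± 0.388, adjusted p = 0.0217).

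Goblet and tuft cell genes fell. Of 16 goblet cell genes 13 fell, or 15 adjusted over the list alone, with a relative median of -0.51 (camera, adjusted p = 0.00672, and adjusted p = 0.615 with an estimated correlation). Clca1, a secreted mucus protein, was 3.49-fold lower (63.0 ± 11.3 against 220 ± 37.5). Tff3, trefoil factor 3, was 1.53-fold lower (616 ± 91.4 against 945 ± 83.2), and Tpsg1 was 1.92-fold lower. Clps, the colipase best known from the pancreas, was 16.1-fold lower. Of the 22 genes of the pancreatic acinar list 3 were measured, too few for the list test, and 2 of these fell. Of 12 tuft cell genes 9 fell, or 10 adjusted over the list alone (relative median -0.38, camera, adjusted p = 0.0205, and adjusted p = 0.557 with an estimated correlation). These included Siglecf, Ptgs1 and Alox5, of which the last 2 encode enzymes of eicosanoid synthesis.

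Angptl4, an inhibitor of lipoprotein lipase, was 11.3-fold higher (13.6 ± 0.647 against 1.196 ± 0.0515, limma adjusted p = 1.4e-06). Pdk4, a kinase that restrains pyruvate oxidation, was 9.33-fold higher (10.7 ± 3.31 against 1.14 ± 0.227, adjusted p = 0.000212), and Pck1, an enzyme of gluconeogenesis, 6.34-fold higher (181 ± 53.9 against 28.6 ± 4.88, adjusted p = 0.000326). Of 24 genes of fatty acid oxidation and ketogenesis 8 rose and 16 did not pass, with 8 adjusted over the list alone (relative median 0.38, camera, adjusted p = 1.76e-08, and adjusted p = 0.553 with an estimated correlation). Beside Angptl4 and Pdk4 these included Acox2, a peroxisomal oxidase, and Ppara, the receptor that controls fatty acid oxidation (4.12 ± 0.364 against 2.34 ± 0.0916). Other large rises were those of the metallothioneins Mt2 (165 ± 31.1 against 16.2 ± 1.44) and Mt1 (276 ± 55.4 against 63.9 ± 3.09) and the kinase Sgk1, which glucocorticoids induce (102 ± 27.6 against 16.1 ± 0.869). Also among them were the translation repressor Eif4ebp3 (21.7 ± 1.78 against 3.34 ± 0.201), the aldo-keto reductase Akr1c19 (85.8 ± 36.6 against 18.2 ± 8.49) and the sulfotransferase Sult6b2 (97.0 ± 72.8 against 10.03 ± 2.37), whose fold went from 9.67 to 5.86 without HET replicate 1.

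Of 20 enterocyte genes 7 rose, of 20 genes of fat absorption 6 rose and 1 fell, and of 22 genes of sugar and peptide absorption 7 rose and 1 fell. Adjusted over the list alone 5, 5 and 6 rose. The relative medians were 0.39, 0.30 and 0.30 (camera, adjusted p = 9e-05, 0.000524 and 0.00106, and adjusted p = 0.553, 0.553 and 0.572 with an estimated correlation). Rbp2, an intestinal retinol carrier, was at 5287 ± 231 in HET and 2998 ± 352 in WT. Apoa1, the major apolipoprotein of high-density lipoprotein, was at 5558 ± 272 and 3709 ± 47.5, and Fabp2, the intestinal fatty acid carrier, at 6794 ± 457 and 4572 ± 287. Npc1l1, the intestinal cholesterol carrier, was the fat absorption gene that fell (97.2 ± 22.2 against 139 ± 7.98, limma adjusted p = 0.0274). It did not pass with median-ratio scaling (adjusted p = 0.068), with a common sum per library (0.0614), or without HET replicate 2 (0.07) or WT replicates 1, 2 or 3 (0.0639, 0.0661 and 0.0915). Dgat2, an enzyme of triglyceride synthesis, was 2.04-fold higher and the fructose carrier Slc2a5 1.70-fold higher. Slc7a9, a carrier of cystine and basic amino acids, fell (87.0 ± 4.07 against 109 ± 5.08). Of 14 genes of the proximal small intestine 3 rose, Rbp2, Sct and Gata4 (61.0 ± 2.79 against 42.9 ± 1.49), with 2 adjusted over the list alone (relative median 0.42, camera, adjusted p = 0.00141, and adjusted p = 0.553 with an estimated correlation). Sct lay near the threshold (limma adjusted p = 0.048) and did not pass without WT replicates 1, 2 or 3 (0.134, 0.112 and 0.0983). Of 6 genes of bile acid transport 3 rose, Cyp27a1, Nr1h4 and Abcc3, with 5 adjusted over the list alone (relative median 0.44, camera, adjusted p = 0.00135, and adjusted p = 0.553 with an estimated correlation).

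Of 17 clock genes 9 rose and 4 fell, or 9 and 5 adjusted over the list alone (relative median 0.49, camera, adjusted p = 0.00201, and adjusted p = 0.553 with an estimated correlation). The repressors Per1 (4.61 ± 0.188 against 1.76 ± 0.0694, limma adjusted p = 8.72e-05) and Per2 (5.55 ± 0.277 against 2.46 ± 0.223, adjusted p = 0.000199) and the output factor Tef rose. The nuclear receptor Nr1d1 fell (23.4 ± 0.345 against 43.0 ± 3.04, adjusted p = 0.000199), as did Arntl, Nfil3 and Nr1d2. Of 14 heat shock genes 10 rose and 3 fell, with the same counts adjusted over the list alone (relative median 0.45, camera, adjusted p = 0.000184, and adjusted p = 0.553 with an estimated correlation). The chaperones Hsph1 (19.1 ± 1.87 against 6.64 ± 0.502) and Hspa8 (583 ± 41.0 against 343 ± 3.58) rose. The small heat shock proteins Cryab and Hspb1, which muscle cells express, fell 2.09-fold and 2.15-fold, and Hspb8 also fell.

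Of 25 cell cycle genes 11 rose and 1 fell, or 12 and 1 adjusted over the list alone (relative median 0.28, camera, adjusted p = 1.31e-05, and adjusted p = 0.553 with an estimated correlation). They included Ccnb2 (30.4 ± 0.632 against 21.2 ± 0.732), Birc5, Ube2c and Aurkb, and the replication licensing gene Mcm4 was the member that fell (7.36 ± 0.1 against 8.98 ± 0.174). Of 26 cytosolic ribosomal protein genes 10 rose, or 8 adjusted over the list alone (relative median 0.42, camera, adjusted p = 3.95e-09, and adjusted p = 0.553 with an estimated correlation). Rpl37 and Rps4x were among them. Of 20 genes of glycolysis and hypoxia 6 rose and 1 fell, also adjusted over the list alone (relative median 0.26, camera, adjusted p = 0.000338, and adjusted p = 0.553 with an estimated correlation). Ndrg1, Pgk1 and Pfkl were higher and P4ha1, a collagen prolyl hydroxylase, was lower. Of 23 genes of oxidative phosphorylation 2 rose, Uqcrc2 and Uqcrq, and 0 passed adjusted over the list alone (relative median 0.18, camera, adjusted p = 0.00135, and adjusted p = 0.604 with an estimated correlation). Not taken relative to all tested genes, their median log2 fold change was only 0.06. Of 19 antioxidant genes controlled by NRF2 4 rose, G6pdx, Gclc, Nqo1 and Pgd, also adjusted over the list alone (relative median 0.25, camera, adjusted p = 0.00722, and adjusted p = 0.553 with an estimated correlation).

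Of 8 genes of antigen presentation by MHC class II 1 rose, H2-DMb1 (112 ± 3.52 against 87.8 ± 3.65), also adjusted over the list alone (relative median 0.29, camera, adjusted p = 0.0102, and adjusted p = 0.557 with an estimated correlation). Of 22 genes of NEDD8, SUMO and ubiquitin conjugation 4 rose and 1 fell, or 3 and 1 adjusted over the list alone (relative median 0.12, camera, adjusted p = 0.044, and adjusted p = 0.553 with an estimated correlation). Not taken relative to all tested genes, their median log2 fold change was only 0.005. Sumo3, Ube2f, Ube2m and Sae1 rose, and Pml, a scaffold of SUMO-rich nuclear bodies whose SUMO-modified form Rnf111 can ubiquitylate, fell (6.41 ± 0.149 against 10.5 ± 0.459). Of 26 genes of xenobiotic metabolism 6 rose and 6 fell, also adjusted over the list alone. Their mean log2 fold change of -0.07 differed in sign from their median of 0.04 and from the test, which was upward (camera, adjusted p = 0.044, and adjusted p = 0.616 with an estimated correlation). Nr1i2, the pregnane X receptor, and the exporter Abcb1a rose, and Cyp2c29 and Cyp2j6 fell, by 10.7-fold and 1.74-fold. Of 5 red blood cell genes 3 rose, or 4 adjusted over the list alone (relative median 1.84, camera, adjusted p = 0.00328, and adjusted p = 0.553 with an estimated correlation). HET replicate 1 held most of the signal, with Hba-a1 at 126 FPKM against 31.9 and 45.2 in HET replicates 2 and 3 and 14.4 to 16.2 in WT, and its fold went from 4.48 to 2.55 without that library. Without HET replicate 1 the log2 fold change of Hbb-bs went from 1.83 to 1.17, that of Hbb-bt from 1.73 to 1.09, that of Abcc3 from 0.51 to 0.31, that of Uqcrq from 0.46 to 0.31 and that of Sct from 0.27 to 0.18.

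**Figure D3:**
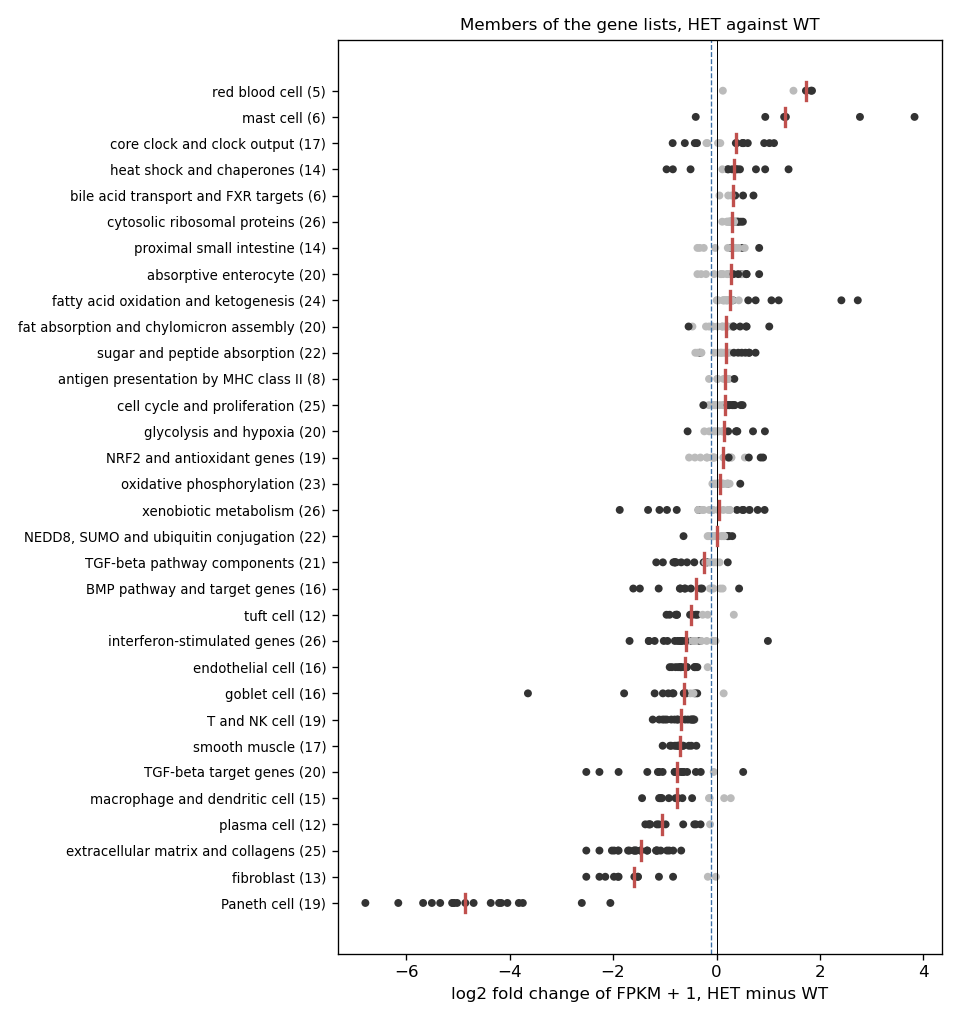
Log2 fold change of FPKM + 1, HET minus WT, of each measured member (dots) of the 31 lists called with the preset correlation and of the BMP list, with the number of measured members after each name, dark dots for members past the threshold and grey dots for the others. Red bars mark list medians and the dashed line the median of all tested genes (-0.12). The Paneth cell list lies lowest and the red blood cell and mast cell lists highest.

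In all, 31 of the 50 lists with at least 5 measured genes were called, 18 upward and 13 downward. The counts of passing members also moved with the scaling. With median-ratio scaling 15 fatty acid oxidation, 11 glycolysis and hypoxia, 7 oxidative phosphorylation, 5 MHC class II, 9 NEDD8, 23 ribosomal, 17 cell cycle and 5 bile acid transport genes rose. So did 5 NRF2, 8 xenobiotic, 8 fat absorption, 8 sugar and peptide absorption, 4 proximal, 4 red blood cell, 1 tuft cell, 2 TGF-beta component and 3 BMP genes. Falls with that scaling numbered 10 for TGF-beta components, 13 for interferon-stimulated, 12 for goblet, 16 for smooth muscle, 12 for endothelial, 17 for T and NK cell, 10 for plasma cell, 5 for xenobiotic and 0 for fat absorption genes. The other counts of these 31 lists and of the BMP list were as given. None (0) of the lists were called with an estimated correlation between genes, where the lowest adjusted p was 0.553 and 3 lists (cell cycle, bile acid transport, and glycolysis and hypoxia) had an unadjusted p under 0.05. The calls of the enterocyte, proximal, fat, sugar, oxidative phosphorylation, NRF2, xenobiotic, MHC class II, NEDD8 and red blood cell lists ended with quantile normalization. Those of the TGF-beta component, clock, NRF2, xenobiotic and NEDD8 lists ended among genes with a mean FPKM of at least 5, and that of the interferon list without HET replicate 1. The xenobiotic list was also not called with median-ratio scaling (adjusted p = 0.124) or a common sum per library (adjusted p = 0.114).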

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

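The length and GC correction, leaving out unnamed loci and the position score were chosen after seeing the data. Genes higher in HET went from 1269 to 2334 with median-ratio scaling, 2929 with quantile normalization and 2090 with array weights, and genes lower in HET went from 4235 to 2153 with quantile normalization and 1853 among genes with a mean FPKM of at least 5, where fewer genes (7341) were tested. For the scalings and array weights the cause was not tested. Leaving out 1 library gave 754 to 1610 genes higher, with 834 without HET replicate 2, 754 without WT replicate 1, 844 without WT replicate 2 and 802 without WT replicate 3, where fewer samples were tested, and 3150 to 4409 genes lower. Lists called went from 31 to 0 with an estimated correlation and were 23 to 34 under the other camera settings. The test fry, which asks whether a list moves on balance in one direction and not whether it moves more than other genes, called 34. It did not call 10 of the 18 upward lists: NRF2 (adjusted p = 0.0685), xenobiotic (0.757), fat (0.0571), sugar (0.197), oxidative phosphorylation (0.35), ribosomal (0.0714), MHC class II (0.0957), NEDD8 (0.785), proximal (0.0987) and red blood cell (0.0709). It called 13 lists that camera did not. These were BMP (fry, adjusted p = 0.00393), Wnt (0.00882), Notch (0.00582), cholesterol (0.0423), immediate-early (0.0248), cytokine (0.0045) and host defence (0.0103). The others were p53 (0.000587), stem cell (0.013), colon (0.0148), enteric neuron and glia (0.00402), interstitial cell of Cajal (0.00521) and B cell (0.00483). Of the reversed results, Rnf111 went from -0.17 to 0.021 with quantile normalization (limma adjusted p = 0.781, against 0.0609). The BMP list turned from down to up by camera among genes with a mean FPKM of at least 5 (camera, adjusted p = 0.752). Camera called it in neither setting. Its relative median was -0.29 before and -0.012 there. The cause of these reversals was not tested. Across named genes and settings, 3478 results kept direction and side of the threshold, 63 lost the call and 49 gained it. Without WT replicate 1 the adjusted p was 0.0548 for Pgd, 0.0514 for Nr1h4, 0.109 for Abcc3, 0.0769 for Uqcrc2, 0.0745 for Uqcrq, 0.0764 for Ube2m, 0.134 for Sct, 0.0694 for Hbb-bs, 0.0757 for Hbb-bt and 0.0762 for the NEDD8 list. Without WT replicate 2 it was 0.05 for Pgd, 0.0805 for Abcc3, 0.0735 for Uqcrc2, 0.0788 for Uqcrq, 0.0505 for Rps4x, 0.0552 for Rpl19, 0.0647 for Rpl18, 0.0526 for Ube2f, 0.112 for Sct, 0.0606 for Hbb-bs and 0.0623 for Hbb-bt. Without WT replicate 3 it was 0.123 for Abcc3, 0.0678 for Uqcrc2, 0.092 for Uqcrq, 0.0578 for Rpl19, 0.0613 for Rpl18, 0.0595 for Ube2m, 0.0983 for Sct, 0.0612 for Hbb-bs, 0.0685 for Hbb-bt and 0.116 for the xenobiotic list. Without HET replicate 1 it was 0.0642 for Sct and 0.0526, 0.0812 and 0.0545 for the NRF2, interferon and NEDD8 lists, without HET replicate 2 it was 0.0757 for Abcc3, 0.0769 for Uqcrc2, 0.067 for Uqcrq and 0.103 for the xenobiotic list, and without HET replicate 3 it was 0.0782 for Sct and 0.0548 for the NEDD8 list. Sae1 gave 0.0545 and 0.0806 without HET replicates 1 and 2 and 0.0973 and 0.12 without WT replicates 1 and 3, and Kit 0.0715 and 0.0737 without WT replicates 1 and 3. These fits hold fewer samples. With quantile normalization the adjusted p was 0.441 for Kit, 0.0949 for Mcm4 and 0.0838 for Nfil3. The call of Sct also ended with the replicate block (0.0619), array weights (0.0937), no filter (0.0696), a mean FPKM of at least 5 (0.0577), eBayes without trend (0.0515) and the position score (0.117). Without a filter the adjusted p was 0.059 for Fabp2, 0.0739 for Abcc3 and 0.0518 for Uqcrq, at a mean FPKM of at least 5 it was 0.055 for Abcc3, with robust eBayes 0.0627 for Hbb-bs and 0.0674 for Hbb-bt, and with the length and GC correction 0.0525 for Ube2m and 0.0557 for Sae1. The xenobiotic call ended with the replicate block (0.0603) and rank-based camera (0.0505), and the interferon and NEDD8 calls with array weights (0.0605 and 0.0568). With the position score the TGF-beta component, NRF2, xenobiotic, oxidative phosphorylation, interferon and NEDD8 lists lost their calls. Whether the replicate numbers pair the samples was not settled. Deviations from the group means correlated at -0.03, 0.13 and 0.32 for same-numbered libraries. HET replicates 2 and 3 correlated best with the WT library of the same number, and HET replicate 1 with WT replicate 2 (0.25). With the number as a block, 1167 genes were higher and 3915 lower, and 30 lists were called. Implied depth, a rough estimate, overlapped between the genotypes, but more rows were at 0 in HET (7295 to 7460) than in WT (6295 to 6688). Weakly expressed genes near an FPKM of 1 rest on few fragments.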

Other observations

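The lists of host defence and inflammatory genes were not called by camera. Among all 11870 tested genes 5504 passed. Of 16 epithelial host defence genes 9 fell and 2 rose, or 9 and 3 adjusted over the list alone (relative median -1.04, camera, adjusted p = 0.275). Genes named in this and the next paragraph were chosen after their values were seen. Duox2, an oxidase of the epithelial surface, and its partner Duoxa2 were at 2.94 ± 1.09 and 3.24 ± 1.36 FPKM in HET against 21.6 ± 10.1 and 24.2 ± 13.9 in WT (SD, n = 3, limma adjusted p = 0.002 and 0.00442). Retnlb, a goblet cell product induced by microbes, was listed at 0 in all 3 HET libraries and at 3.22, 1.18 and 5.72 in WT. Gsdmc2, Gsdmc3 and Gsdmc4, gasdermins of the intestinal epithelium, fell (limma adjusted p = 0.000265, 0.000148 and 0.000226), with Gsdmc2 at 1.46 ± 0.724 against 21.9 ± 6.79. Of 13 cytokine and chemokine genes 9 fell and 1 rose, or 9 and 2 adjusted over the list alone (relative median -0.59, camera, adjusted p = 0.275), including Cxcl9 (3.29 ± 1.29 against 11.4 ± 1.69) and Il18 (36.3 ± 8.38 against 84.2 ± 1.72).

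Of 13 intestinal stem cell genes 6 fell, or 7 with 1 rise adjusted over the list alone, and of 14 Wnt targets 6 fell and 3 rose, or 8 and 3 adjusted over the list alone (camera, adjusted p = 0.339 and 0.669). Lgr5, the stem cell marker, fell (0.494 ± 0.0882 against 1.68 ± 0.0552, limma adjusted p = 0.000232) while Myc rose (20.8 ± 1.86 against 9.59 ± 0.376, adjusted p = 0.000178). Of 14 p53 targets 7 fell and 1 rose, or 8 and 2 adjusted over the list alone (adjusted p = 0.277), with Trp53inp1 at 2.63 ± 0.163 against 14.3 ± 0.382. Of 16 immediate-early genes 9 fell, Egr1 among them (1.16 ± 0.230 against 3.10 ± 0.381, camera, adjusted p = 0.101 for the list), or 10 adjusted over the list alone. Of 11 colon epithelium genes 6 fell and 1 rose, or 6 and 2 adjusted over the list alone (adjusted p = 0.775), and of 14 distal small-intestinal genes 2 fell, or 0 adjusted over the list alone (adjusted p = 0.864). With median-ratio scaling 4 p53 targets fell and 2 rose, 7 immediate-early genes and 5 Wnt targets fell, 2 stem cell and 3 colon genes rose, and 1 distal gene fell and 1 rose.

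In the following, the tests of other splits, of tissue outside the epithelium, of Paneth genes outside the defensins and of the time of tissue collection were chosen after the result was seen. More genes were lower than higher in HET. Correcting for gene length and GC content left 4015 genes lower, against 3997 of the same genes without it. That correction kept each library's mean level, so it could not remove a shift common to all genes. Across genes, log2 fold change correlated with transcript length at a Spearman rho of -0.197 and with GC content at 0.06. Length and GC content were therefore not settled as a cause. Median-ratio scaling gave 58.3% lower, but it centres the libraries (median log2 fold change from -0.12 to -0.03). It so shifts this share whatever the cause, and the deposited scaling stays open. A smaller share of tissue outside the epithelium could lower its cell types alike. Fibroblast genes lay below endothelial genes (difference of median log2 ratios -1.21, 95% bootstrap interval over genes -1.57 to -0.43). This argues against such an even fall as the whole cause. The interval treats the genes of a list as independent, and an uneven loss of cell types was not tested. A smaller share therefore stays open. The medians were -2.10 for fibroblast, -0.89 for endothelial, -0.82 for smooth muscle, -0.82 for T and NK cell, -0.78 for macrophage, -1.31 for plasma cell and 4.02 for mast cell genes. Of the 10 splits of the 6 libraries, 1, the real one, gave as many genes (5504, against at most 1 in the others), and 10 splits are too few for a share under 0.05; an effect of the substitution stays open and was not tested apart from these.

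Paneth cell genes fell most. With the position score as a covariate all 19 still passed, and their median log2 fold change went from -4.86 to -3.71. Within each genotype Ang4 rose with the score. Yet HET replicate 3 (score -0.35) held Ang4 at 14.8 FPKM, against 720 in WT replicate 1 (score -0.47). This argues against position, as the score measures it, as the whole cause. The score is a mean of marker genes in 6 libraries and may miss differences in position, so a part stays open. Reads shared between defensins or a variant of their cluster would spare other Paneth genes, but the 6 members outside the family (Lyz1, Mmp7, Ang4, Itln1, Mptx2 and Pla2g2a) all fell, with a median of -3.99. A loss of Paneth cells or of their products in HET and an unlabelled difference in housing, microbes or dissection stay open, and neither was tested.

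Clock genes changed in both directions, with 9 of 17 higher and 4 lower. All 13 called clock genes stayed called under both the length and GC correction and median-ratio scaling, so their calls did not rest on either. Of all 5504 called genes, 4751 and 4536 also stayed called in these settings. Staying called thus does not set the clock genes apart and says little about a trend of the whole libraries. The clock list held more called members than 98.2% of 10000 random lists matched on expression, which an effect of the substitution would give as well as tissue taken at another time of day or after a longer fast. These cannot be told apart, because the labels give no time of collection or feeding.

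Among the 50 tested genes nearest to Rnf111, 25 on each side, 26 (52.0%) were called against 46.3% of the others (one-sided Fisher's exact p = 0.255), so sequence variants linked to the locus can be neither seen nor excluded. The largest absolute log2 fold change among these 50 was that of Bmp5 (-1.48), and Ccnb2 (0.50) was also among them. Prg2, an eosinophil granule protein chosen after its values were seen, rose (12.1 ± 4.58 against 3.76 ± 0.0574, limma adjusted p = 0.00477) and Siglecf fell, with 2 genes of their list measured. Lists not called by camera and not described above were those of Notch (adjusted p = 0.664), cholesterol synthesis (adjusted p = 0.775), the unfolded protein response (adjusted p = 0.531), tight junctions (adjusted p = 0.775), enteroendocrine cells (adjusted p = 0.133), enteric neurons and glia (adjusted p = 0.277), interstitial cells of Cajal (adjusted p = 0.277), adipocytes (adjusted p = 0.119), mesothelium (adjusted p = 0.665) and B cells (adjusted p = 0.142). The unfolded protein response list held 23 measured genes, of which 10 fell and 5 rose, or 7 and 8 with median-ratio scaling. Herpud1, a member of it, rose (86.2 ± 3.02 against 49.7 ± 1.97). The tight junction list held 17 measured genes, of which 3 fell and 1 rose, or 1 and 1 with that scaling. Cldn4, a tight junction claudin, fell (23.1 ± 12.7 against 65 ± 1.64). Herpud1 and Cldn4 were chosen after their values were seen.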
